A study of Gallus gallus with 3 samples.

How the data were processed

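RNA of 3 antibody-sorted chicken cell populations was labelled with Cy3 and hybridised to Agilent gene expression arrays of 1 colour, with 1 array per population, per the labels. Groups were taken from the sample titles. The values in the deposited scanner files are spot intensities. The processed intensity is background-subtracted and detrended within each array, with surrogate values for dim spots, and is not normalized between arrays, per the file headers. These name Agilent Feature Extraction 10.7.1.1, while the submitters' processing notes name version 9.1. Probe coordinates are those of the files, on galGal3. The deposited series table holds log2 values of the same arrays. Set against each array's own processed signal, its columns had a rank correlation that rounded to 1, against 0.855 to 0.899 with the other arrays. Each column had a median of 8.47, so the authors' deposited log2 values were read as quantile-normalized processed signals. Their exact procedure is not given in the sources used here.

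For the main values, log2 of the processed signal was averaged over the spots of a probe that were not flagged as outliers, and the array's 75th percentile over probes was subtracted. That percentile was a processed signal of 2163.4 on the ESC array, 1696.8 on the PGC array and 3421.9 on the SSC array. Control spots, 1417 per array, were left out. A probe counted as measured where most of its spots were well above background by the scanner software's flag. Probes repeated on the array gave a spot SD of 0.095, 0.101 and 0.144 log2 units on the ESC, PGC and SSC arrays. The lowest scaled signal of a measured probe was -7.22, -6.71 and -6.73. Where a gene had no measured probe on 1 array, only a bound is given, the bright signal against the higher of that floor and the dim probe's own signal.

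Genes were named through the RefSeq gene table of assembly GRCg7b, used for names only: 11013 probes by the probe's accession, 12549 by gene name, 919 by gene number and 1229 by another listed accession. The other 17893 kept the file's name, which can be old. Synonyms were not used for naming, because they gave some probes the symbol of another gene (the ZBTB16 probes, for example). This was decided after the values had been seen. Aliases in the gene lists that are symbols of other genes, 7 in all, were left out. Of 27743 genes or names, 8908 had 2 or more probes, and the probe with the highest mean log2 signal over the 3 arrays stood for the gene. Where that probe gave a difference of at least 2-fold, the next brightest measured probe had the same sign for 94.6% of genes for PGC minus ESC, 93.9% for SSC minus PGC and 95.0% for SSC minus ESC.

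The 3 comparisons were PGC minus ESC, SSC minus PGC and SSC minus ESC. With 1 array per group no test and no p-value was computed, genes at least 2-fold apart were counted, and genes measured on both arrays entered the counts. The 27 gene lists and the rule for named genes were fixed before the data were examined. For each list the median log2 difference is given with its percentile among 10000 random lists of the same size, matched on mean signal in 20 bins. The percentile describes these arrays, not the stages. The standard error of a median comes from 1000 bootstrap draws of the list's genes. Lists share some members, such as 3 genes in the pluripotency and spermatogonial lists. Named were the 5 largest differences each way among genes with a symbol whose measured probes had one sign (3 for SSC minus ESC), the 3 largest bounds each way, members at the ends of each list, the 3 largest margins per stage, and 14 genes in any case. Of these PRDM1 was not found by name. One gene that the rule picks is not reported here. In the simulated PGC minus ESC comparison of 23823 genes, with spot noise of 0.15 log2 units, all 100 genes raised 4-fold and all 100 lowered 4-fold were recovered, with 0 false calls. This checks the code only. The simulated array was the ESC array with noise added. In the real comparisons the SD per probe was larger, 0.55 to 0.65, so the 0 false calls give no error rate for these data. A list of 40 genes shifted by 0.6 reached percentile 100 and an unshifted list 14.9.

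The results were computed again with normexp background correction of the spot and local background intensities, offset 50 (limma 3.58.1, R 4.3.3), quantile normalization, scaling by the median, the deposited log2 values, no filter on dim probes, genes measured on all 3 arrays, and the median over a gene's probes. Scaling by 5 spike-in control probes was added after seeing the data. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Leaving out replicates, pairing and other splits of the samples do not apply to 1 array per group.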

Results

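RNA of 3 chicken cell populations, each sorted by fluorescence with antibodies, was hybridised to 1-colour Agilent expression arrays, with 1 array per population. The populations were embryonic stem cells (ESCs) of day 0, primordial germ cells (PGCs, the embryonic precursors of eggs and sperm) of day 4, and spermatogonial stem cells (SSCs, the self-renewing germ cells of the testis) of day 18.5. The labels call all 3 male. Each array had 45220 spots, of which 43803 carried 43603 probes. Probes well above background made up 86.96% of the probes on the ESC array, 86.85% on the PGC array and 86.25% on the SSC array, and no probe spot was saturated. The design text speaks of several independent experiments per stage, while 1 array per stage was analysed here, and whether its RNA was pooled is not stated. No value below therefore has a replicate error, no test of the stages could be made, and the number of arrays limits the precision. The technical error was estimated within the arrays. The scanner software's own error of a log2 difference had a median of 0.205. The difference between 2 probes of one gene gave an SD per probe of 0.65 for PGC minus ESC, 0.55 for SSC minus PGC and 0.618 for SSC minus ESC. Signals are given as log2 values relative to the array's 75th percentile, and a positive difference means higher on the array named first. Differences of at least 2-fold, or 1 on the log2 scale, are counted below. This size is above each of these technical errors but not far above the SD per probe. Technical error alone can therefore bring some genes into the counts.

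Across the 21653 genes measured on all 3 arrays, Pearson's r of the log2 signals was 0.841 between ESC and PGC, 0.877 between PGC and SSC and 0.831 between ESC and SSC. These correlations are across genes, which are not independent replicates.

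The comparison of PGCs with ESCs asked how expression differed between the germ cell precursors and the cells of the day 0 embryo. Globin genes were far higher and genes of the early embryo far lower on the PGC array. The 5 largest positive differences were those of the globin genes HBZ (13.92), HBAA (12.87), HBE1 (10.43) and HBA1 (10.21) and of AvBD10 (11.46), a beta-defensin, an antimicrobial peptide. HBAA and HBA1 are aliases in the erythroid list and may be the same gene. The 5 largest negative differences were those of EOMES (-10.04), a T-box transcription factor of the early embryo, OTX2 (-9.46), a homeobox factor of the early embryo and forebrain, the cyclin gene CCNA1 (-9.40), POUV (-7.87), the chicken POU5F3 that acts in pluripotency, and SOX3 (-7.18). OTX2 (-6.02) and POUV (-6.19) stood near the floor of -6.71 on the PGC array, so the sizes of their differences are uncertain. The EOMES probe lies on chromosome 2 at 38594027 to 38594086 and the HBZ probe on chromosome 14 at 12723932 to 12723991, both in the galGal3 build. The probes of DDX4 and DAZL, named below, lie there on chromosome Z at 16295784 to 16295843 and on chromosome 2 at 34385308 to 34385367. Where the ESC array had no probe of a gene well above background, AvBD7 and CYP1A2 were higher on the PGC array by at least 10.29 and 10.01 log2 units. In the other direction, VSTM2A, KCNA10 and the Wnt ligand gene WNT3A were lower on the PGC array by bounds of -6.61, -6.39 and -6.02. Of 22490 genes measured on both arrays, 6530 were at least 2-fold higher and 4817 at least 2-fold lower on the PGC array. The median of all genes was 0.25, and with quantile normalization, which sets it to 0.02, the split was 5211 higher and 5376 lower. Scaling by spike-in control RNA, tried after seeing the data, raised every difference by 0.86 and made 85.4% of the genes at least 2-fold apart higher, against 57.5%, and of the list medians given below those of meiosis and of DNA methylation and chromatin turned positive with it.

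Pluripotency genes were lower on the PGC array as a group. Of 22 measured members 15 were at least 2-fold lower and 3 higher, with a median of -2.36 (bootstrap SE over genes 0.59), at percentile 0.0 of 10000 random lists matched on signal. Besides OTX2 and POUV, NANOG stood at -5.07, LIN28A, an RNA-binding protein of stem cells, at -4.04, and SOX2 at -2.34. The highest members were KLF2 at 3.18 and CDH1, E-cadherin, at 2.35, although the other CDH1 probes gave -0.04 and -0.16.

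Several germ cell genes were also lower on the PGC array. Of 16 members measured on both arrays, 8 were at least 2-fold lower, 3 at least 2-fold higher and 5 within 2-fold, and 5 more were well above background on the ESC array only. The median was -0.93 (SE 0.53, percentile 1.2), within 2 SE of 0, and -0.07 with spike-in scaling. TFAP2C stood at -4.40 and DAZL, an RNA-binding protein of germ cells, at -3.99. DDX4, the vasa homologue used as a germ cell marker, was not well above background on the PGC array and had a bound of -2.61. The receptor gene KIT had a bound of -3.91, MAEL one of -3.71 and BRDT one of -5.74. DMRT1, a Z-linked gene of testis development, was highest at 2.21, although one of its 4 probes gave -0.57, and TDRD5 was 3.40-fold higher. PIWIL1, which acts in the piRNA pathway, stood at -0.71. The spermatogonial list went both ways, with 9 of 21 members at least 2-fold higher and 5 lower (median 0.55, SE 0.67, percentile 76.7). Its highest members were GFRA1, the receptor of GDNF, at 4.04 and ID4 at 4.03, its lowest EOMES and SALL4 (-4.78), and ZBTB16 stood at 1.27. Of 14 meiosis genes 9 were within 2-fold (median -0.13, SE 0.34, percentile 24.0), and STRA8, SYCP3 and the mesoderm gene TBXT stood at 0.29, 0.08 and -0.51.

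Markers of several other cell types were higher on the PGC array. The erythroid list had a median of 5.30 (SE 2.29, percentile 100), with 11 of 16 members at least 2-fold higher. KLF1 (-3.87) and HEMGN (-3.16) were its lowest members. The mesenchymal and fibroblast list had a median of 3.35 (SE 0.88, percentile 100), with 17 of 23 members higher and 0 lower, led by ACTA2, smooth muscle actin, at 8.24 and COL5A1 at 7.41. The endothelial list stood at 2.44 (SE 0.79, percentile 100), led by CDH5, the endothelial cadherin, at 6.90 and SOX18 at 5.12. The leukocyte list stood at 1.44 (SE 0.80, percentile 99.9), within 2 SE of 0, with CTSS at 6.55 and CD3E at -1.89. The Sertoli cell list stood at 1.12 (SE 0.55, percentile 99.2), with 10 of 18 members at least 2-fold higher and 3 lower. Its members went both ways, with EMX2 at 4.54 and GDNF at 4.21 highest and FSHR at -2.89 and AMH at -2.70 lowest. The other AMH probes measured on both arrays gave 1.03 and 1.18. The steroidogenic (0.90, SE 0.37, percentile 94.6) and neural lists (0.78, SE 0.34, percentile 92.5) lay within the middle 95% of random lists.

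All 26 HOX genes measured on both arrays, transcription factors that pattern the body axis, were at least 2-fold higher on the PGC array (median 3.67, SE 0.35, percentile 100). HOXB4 stood at 8.07 and HOXA9, the lowest, at 1.09. Another 3 HOX genes were well above background on the PGC array only and 2 on the ESC array only, of which HOXC12 had a bound of -0.84. Retinoid genes had a median of 1.78 (SE 0.66, percentile 100), from UGT1A1 at 8.28 and ALDH1A1, a retinaldehyde dehydrogenase, at 7.38 to CYP26B1, which degrades retinoic acid, at -3.74. Oxidative phosphorylation genes had a median of 1.26 (SE 0.17, percentile 100), with 33 of 52 higher and 0 lower, and COX6C stood at 2.53. With quantile normalization this median was 0.87, with 19 of 52 higher. Ribosomal protein genes had a median of 0.97 (SE 0.03, percentile 98.8), which was 0.08 with quantile normalization. Cell cycle genes were lower, with 21 of 44 members at least 2-fold lower and 6 higher (median -0.90, SE 0.26, percentile 0.0), and the median was -0.04 with spike-in scaling. Among them CDC25A stood at -3.83 and CCNE2 at -3.47, and CHEK1 at 1.75. DNA methylation and chromatin genes had a median of -0.43 (SE 0.15, percentile 3.2). The remaining lists lay within the middle 95% of random lists: TGF-beta, Nodal and BMP at 0.20 (percentile 49.1), Wnt at 0.26 (64.5), JAK-STAT at 0.28 (76.7), Notch at 0.15 (51.4), FGF and MAPK at 0.08 (31.0), CDK inhibitors and apoptosis at 0.45 (85.1), gastrulation and extraembryonic endoderm at 0.19 (37.7), glycolysis at 0.08 (26.4), and dissociation and heat shock at 0.53 (64.6). Within the gastrulation list TTR stood at 8.40 and CDX2 at -5.76.

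**Figure D1:**
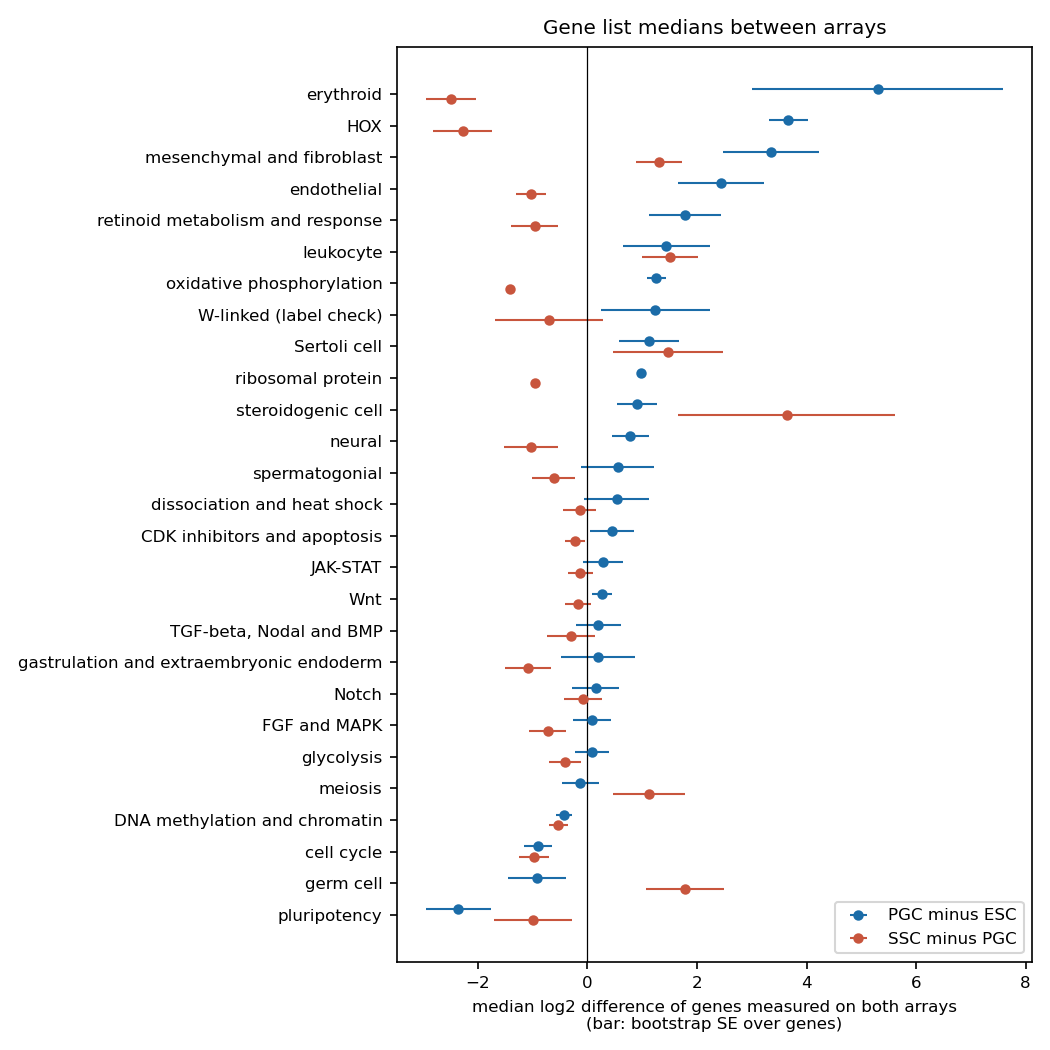
Median log2 difference (horizontal axis) of the 27 gene lists for PGC minus ESC (blue) and SSC minus PGC (red), over members measured on both arrays, with bootstrap standard errors over genes as bars. The pluripotency list lies at -2.36 and -0.99, the germ cell list at -0.93 and 1.78, and the erythroid list at 5.30 and -2.49.

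The comparison of SSCs with PGCs asked how expression differed between the germ cells of the late embryonic testis and their day 4 precursors. Germ cell genes and several genes of testis cells were higher on the SSC array, and globin and HOX genes lower. The 5 largest positive differences among genes whose probes all had one sign were those of SLCO1A2 (8.55) and SLCO4A1 (6.84), organic anion transporters, CTSG (8.14), a granule protease of white blood cells, GCNT2 (7.17) and INHA (6.71), the inhibin alpha subunit. On the PGC array SLCO1A2 stood at -6.70 and CTSG at -6.17, near the floor of -6.71, so the sizes of these 2 differences are uncertain. Among the 5 largest negative ones were those of HBZ (-13.21), UPK3B (-8.27), TMEM52B (-8.04) and TM6SF2 (-7.70). The meiotic cohesin gene SMC1B was at least 7.48 higher on the SSC array, TACR3 at least 6.45 and IL9 at least 6.16. A probe that the files name ATP5A1 and place nowhere in the genome had the largest bound in the other direction, -10.97, followed by HSD11B1B at -7.11 and PLET1 at -7.09. Of 22334 genes measured on both arrays, 4292 were at least 2-fold higher and 5244 at least 2-fold lower on the SSC array, with a median of all genes of -0.17. With spike-in scaling, which raised every difference by 0.78, 81.9% of the genes at least 2-fold apart were higher, against 45.0%, and list medians between -0.78 and 0 turn positive, among them the spermatogonial one.

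Germ cell genes were higher on the SSC array. Of 16 measured members 11 were at least 2-fold higher and 2 lower, and 5 more were well above background on the SSC array only (median 1.78, SE 0.72, percentile 100). DAZL stood at 6.18, DMRT1 at 4.49, with one of its probes at -0.39, and PIWIL1 at 4.32. DDX4 was at least 5.20 higher, KIT at least 4.76 and MAEL at least 4.68. SOX17 (-1.90) and the chemokine receptor gene CXCR4 (-1.03) were the lowest. Meiosis genes had a median of 1.12 (SE 0.66, percentile 99.7), within 2 SE of 0, with 7 of 14 members at least 2-fold higher and 2 lower. HORMAD1 and SYCP3, parts of the meiotic chromosome axis, stood at 4.81 and 4.21, STRA8 at 2.85, and MSX2 and MSX1 at -3.73 and -2.15. The spermatogonial list did not stand apart (median -0.62, SE 0.40, percentile 20.2), with 3 of 19 members higher and 7 lower. DMRT1 and CD9 (2.42) were its highest members and CDH1 (-4.28) and POU3F1 (-3.46) its lowest, while ZBTB16 stood at 1.63, with one of its probes at -0.27, and GFRA1 at -0.89. Of 18 measured pluripotency genes 9 were at least 2-fold lower and 3 higher (median -0.99, SE 0.71, percentile 0.8). This median lay within 2 SE of 0 and was -0.21 with spike-in scaling. EPCAM stood at -4.14, LIN28A at -3.24 and SOX2 at -1.01. NANOG had a bound of -1.15, and TBXT stood at -0.48. The 3 higher members were POUV at 2.21, KLF2 at 1.02 and OTX2 at 1.01. On the PGC array POUV stood at -6.19 and OTX2 at -6.02, near the floor of -6.71, so the sizes of their differences are uncertain.

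**Figure D2:**
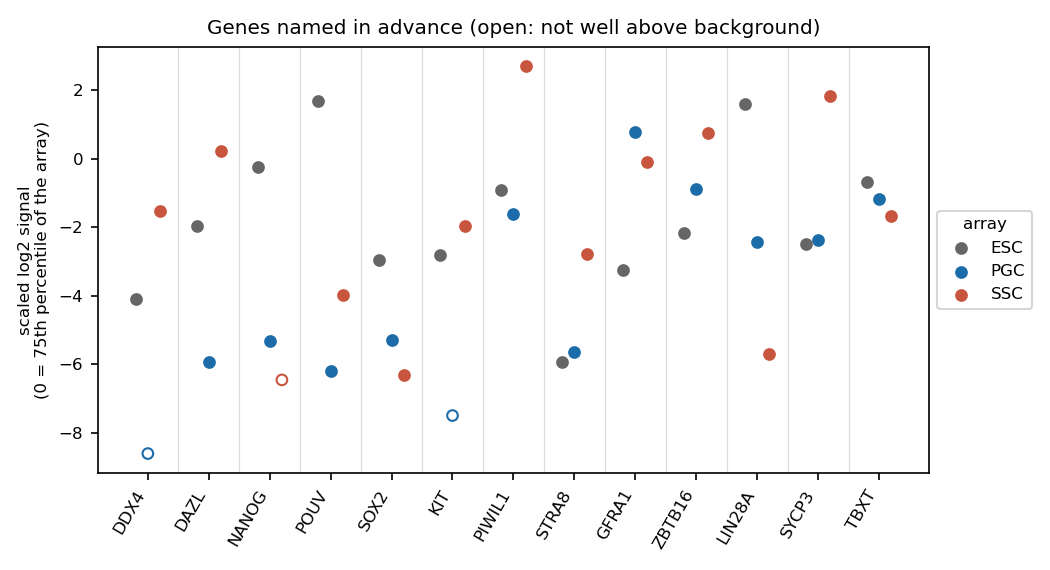
Scaled log2 signal (vertical axis, 0 at the array's 75th percentile) of the 13 genes on the array that were to be named whatever their values, on the ESC, PGC and SSC arrays, with open circles where the probe was not well above background. Levels compare between arrays within a gene, not between genes. DDX4 and KIT are open on the PGC array, and DAZL lies at -1.95, -5.94 and 0.24.

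Several markers of the somatic cells of the testis were higher on the SSC array beside the germ cell genes. The medians of the steroidogenic and Sertoli cell lists, however, both lay within 2 SE of 0. The steroidogenic list had a median of 3.64 (SE 1.98, percentile 100), with 6 of 11 members at least 2-fold higher and 2 lower. CYP17A1, an enzyme of androgen synthesis, stood at 6.34 and LHCGR, the luteinising hormone receptor, at 5.95. The Sertoli cell list had a median of 1.47 (SE 1.0, percentile 100), with 11 of 18 members higher and 4 lower, led by AMH, anti-Müllerian hormone, and INHA and with CLDN1 lowest at -3.20. The brightest AMH probe gave 10.23 and the other AMH probes measured on both arrays 3.96 and -0.30, so that its size depends on the probe. The mesenchymal list stood at 1.31 (SE 0.42, percentile 100), with OGN at 5.09, and the leukocyte list at 1.5 (SE 0.51, percentile 100), with LYZ, lysozyme, at 3.67. Other lists were lower on the SSC array. The erythroid list stood at -2.49 (SE 0.46, percentile 0.0), with 13 of 16 members at least 2-fold lower. The endothelial list stood at -1.03 (SE 0.28, percentile 0.2), although PECAM1 stood at 2.79, and the neural list at -1.03 (SE 0.49, percentile 0.3), with NES at -3.98.

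Of 22 HOX genes measured on both arrays, 20 were at least 2-fold lower on the SSC array and 0 higher (median -2.28, SE 0.54, percentile 0.0), from HOXD8 at -7.63 to HOXA9 at -0.84. Retinoid genes stood at -0.96 (SE 0.43, percentile 0.0), with RDH12 at 4.66 and UGT1A1 at -5.76. Oxidative phosphorylation genes had a median of -1.41 (SE 0.07, percentile 0.0), with 40 of 51 lower and 0 higher. With quantile normalization this median was -0.53, with 9 of 51 lower. Cell cycle genes stood at -0.98 (SE 0.27, percentile 0.1), with 22 of 44 lower and 0 higher, and PLK1, a mitotic kinase, at -2.79. With spike-in scaling the cell cycle median was -0.20. Gastrulation genes stood at -1.08 (SE 0.42, percentile 0.1), with TTR at -5.76, and FGF and MAPK genes at -0.73 (SE 0.33, percentile 1.2), with FGF8 at -3.91 and EGR1 at 2.48. Ribosomal protein genes stood at -0.95 (percentile 70.8), and 0.02 with quantile normalization. The dissociation and heat shock list stood at -0.14 (percentile 99.5), high for its signal, and turned to 0.45 with quantile normalization. The other lists lay within the middle 95% of random lists: TGF-beta, Nodal and BMP at -0.30 (percentile 38.8), Wnt at -0.17 (52.0), JAK-STAT at -0.13 (39.4), Notch at -0.08 (53.5), CDK inhibitors and apoptosis at -0.23 (58.0), DNA methylation and chromatin at -0.53 (5.3) and glycolysis at -0.41 (83.5). Single members with large differences were the prolactin receptor gene PRLR at 5.65 and SOCS2 at -5.69 in JAK-STAT, WNT11 at -5.13 in Wnt and GREM1 at -4.91 in the TGF-beta list.

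SSCs were also compared with ESCs, the last stage with the first. CATHL2 and CATH2, names in the files for overlapping cathelicidin probes, stood at 11.53 and 10.87 and ALDH1A1 at 10.37. CDX2, a homeobox factor of the early embryo, stood at -11.03, EOMES at -9.46 and SOX3 at -9.18. Pluripotency genes had a median of -4.26 (SE 1.21, percentile 0.0), with 15 of 18 members at least 2-fold lower and 1 higher. Germ cell genes had a median of 1.91 (SE 0.59, percentile 100), with 12 of 20 members higher and 3 lower. Markers of other cell types were higher too, each list at percentile 100. The mesenchymal list stood at 5.52 (SE 1.62, 22 of 23 higher), leukocyte at 3.25 (SE 1.54, 13 of 18), Sertoli cell at 2.89 (SE 0.80, 15 of 18) and endothelial at 1.83 (SE 0.79, 10 of 16). The steroidogenic (2.35, SE 1.94, 5 of 10 higher and 1 lower) and erythroid medians (1.92, SE 1.60, 9 of 16 higher and 3 lower) lay within 2 SE of 0. Of the germ cell genes DDX4 stood at 2.59, DAZL at 2.19 and PIWIL1 at 3.61. The spermatogonial median was 0.08 (SE 0.42, percentile 71.7), with ZBTB16 at 2.91, one of its probes at -0.04, and GFRA1 at 3.16. Cell cycle genes stood at -2.42 (SE 0.34, percentile 0.0), with 34 of 44 lower and 0 higher. Of 22247 genes measured on both arrays, 5439 were at least 2-fold higher and 5084 at least 2-fold lower, so that 51.7% of the genes at least 2-fold apart were higher. Scaling by the array median made this 39.8%, from 4345 higher and 6581 lower, and spike-in scaling 95.0%.

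Genes at least 4-fold higher on 1 array than on both others numbered 802 for ESC, 638 for PGC and 787 for SSC, of the 21653 measured on all arrays. The largest margins were those of EOMES (9.46), OTX2 (8.45) and SOX3 (7.18) on the ESC array. They were HBZ (13.21), TMEM52B (8.04) and TM6SF2 (7.46) on the PGC array and SLCO1A2 (7.96), AMH (7.53) and INHA (6.71) on the SSC array.

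A list of genes on the female-specific W chromosome served to check the label male, since female birds are ZW and male birds ZZ. Only 5 of its 17 members were found on the array, and its medians of 1.24 for PGC minus ESC (percentile 93.3) and -0.70 for SSC minus PGC (percentile 35.3) did not stand apart. The probes of HINTW, described in detail after its values were seen, disagreed in size. Of its 7 probes, 5 were bright on the ESC array (4.81 to 5.66) and the PGC array (7.40 to 8.13) and at -8.71 to -2.42 on the SSC array, where 2 of them were not well above background. Their signal was at least 1211-fold higher on the PGC than on the SSC array. The other HINTW probes stood at 6.46 and 7.93 on the PGC array and at 2.94 and 4.77 on the SSC array, 11.4-fold and 9.0-fold lower, so that all 7 were lower there. UBE2R2L, another W-linked gene, was lower on the SSC than on the PGC array by a bound of -3.78, while ATP5A1W stood at -1.21, FET1 at -0.18 and SPIN1L at 0.75, with its other probes at -0.43 and -2.38. In galGal3 the FET1 probe lies on chromosome 4, at 64949459 to 64949518, and not on W. It may not bear on the label, although FET1 counts in the medians of the list.

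**Figure D3:**
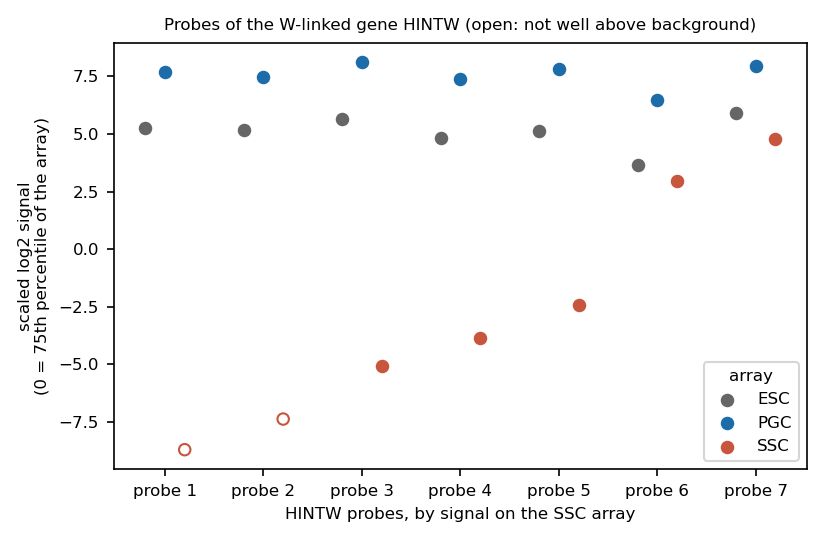
Scaled log2 signal (vertical axis, 0 at the array's 75th percentile) of the 7 HINTW probes on the ESC, PGC and SSC arrays, ordered by their signal on the SSC array, with open circles where a probe was not well above background. On the SSC array 5 probes lie between -8.71 and -2.42, and the others at 2.94 and 4.77.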

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

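The tests of quantile normalization and of probe GC content in the third pattern were written down before their results were seen, and the other tests here were chosen only after the result was seen. With 1 array per stage, stage and array cannot be separated, and differences between the stages themselves stay open as untested explanations.

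The spike-in control spots, which the comparisons do not use, carried a signal that differed between arrays. After scaling by the 75th percentile, 5 of 10 spike-in probes, those with a log2 signal between 6 and 17 on every array, were on average -0.86 log2 units apart for PGC minus ESC (SD 0.10) and -0.78 for SSC minus PGC (SD 0.07). This range was chosen after seeing the data, and not all probes outside it went the same way, as a brighter one had 7.86 on the ESC and 8.55 on the PGC array and another 7.41 on both.

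The first pattern is that markers of other cell types stood high on the PGC and SSC arrays, although the cells were sorted with antibodies. In the same pattern, several germ cell genes were low on the PGC array. The germ cell median PGC minus ESC was -0.93 (SE 0.53), within 2 SE of 0, and -0.07 with spike-in scaling. It covers the 16 members measured on both arrays. Left out are 5 members well above background on the ESC array only, DDX4 and KIT among them, against 0 on the PGC array only. Without the filter on dim probes the median was -1.15. A hybridisation of the PGC array so weak that probes fell to background is argued against. Its share of probes well above background differed from that of the ESC array by -0.11 percentage points. This share does not follow overall signal, so it cannot exclude a dimmer PGC array. The 75th percentile of processed signal was lowest on the PGC array, 1696.8 against 2163.4 on the ESC and 3421.9 on the SSC array. An exchange of the PGC and SSC labels stays open, since the median SSC minus PGC of the 28 measured Sertoli and steroidogenic genes, 1.47 (percentile 100 of matched lists), lay within 2 bootstrap standard errors (2.10) of 0, although 20 of the 28 were above 0, among them AMH (10.23 by its brightest probe), INHA (6.71) and CYP17A1 (6.34), as the labels would have it. Somatic testis cells in the SSC sample stay open too, since the count of genes of these lists at least 4-fold higher on the SSC than on the PGC array, 13 of 29 with 2 at least 4-fold lower, restates the pattern. Blood cells may have contributed to the PGC sample, which stays open. Of the 7 globin genes of the erythroid list 3 were at least 16-fold higher than on both other arrays, between the bounds for and against. The test cannot decide, since globin signal on the SSC array lowers this count. There HBAD stood at 6.32, HBBA at 6.02, HBAA at 4.46, HBE at 4.29 and HBE1 at 1.33, while HBZ (-4.66) and HBG1 (-6.53) were dim. Against the ESC array all 7 were higher, from a bound of 5.66 for HBG1 to 13.92 for HBZ. HBA1, which the list holds only as an alias of HBAA and which is not counted apart, stood at 10.21 for PGC minus ESC and -1.67 for SSC minus PGC.

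The second pattern is the W-linked signal on arrays labelled male. Signal of a Z-linked copy on the HINTW probes is argued against for 5 of the 7 probes, which were at least 16-fold lower on the SSC than on the PGC array while the others, still bright there, were 11.4-fold and 9.0-fold lower. Female cells in the PGC and ESC samples would also lower Z-linked genes there. The Z minus autosomal median was 0.946 (bootstrap SE over genes 0.044) for SSC minus PGC and 0.466 (SE 0.054) for SSC minus ESC, where 27 autosomes ranged from -0.744 to 0.254 and from -0.205 to 0.162, and 0.675 and 0.369 after removing the trend with probe GC content and signal. RNA of female embryos in the PGC and ESC samples is a hypothesis these values leave possible, but for PGC minus ESC the Z minus autosomal median was -0.455 (SE 0.078, autosomes -0.164 to 0.486, and -0.271 after removing the trend), which equal shares of female cells would not give, and a stage difference in Z-linked expression was not tested.

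The third pattern is that oxidative phosphorylation genes were higher on the PGC array than on both others. A trend with brightness is argued against as the whole cause, since the PGC minus ESC median was 0.87 (SE 0.10, percentile 100) with quantile normalization, against 1.26 without. The GC content of the probes is argued against as the whole cause likewise, with a median of 0.78 (SE 0.12) after removing the trend with GC content and signal. On the SSC side the corrections took away most of the pattern, as the SSC minus PGC median of -1.41 became -0.39 (SE 0.10) after removing that trend and -0.53 with quantile normalization. Part of the pattern may thus be technical, and the makeup of the sorted sample stays open.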

How the results depend on the processing

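The counts of genes at least 2-fold apart stayed within 1.5 times under the 7 other settings chosen before the data were examined and moved further with spike-in scaling, chosen after seeing the data. The median of all genes for PGC minus ESC went from 0.25 to 0.02 with quantile normalization, median scaling or the deposited values, and that for SSC minus ESC from 0 to -0.31 with median scaling. Spike-in scaling raises every difference by one amount, 0.86 for PGC minus ESC, 0.78 for SSC minus PGC and 1.64 for SSC minus ESC. It gave 11892 higher and 2041 lower genes for PGC minus ESC (85.4% higher), 8512 and 1884 for SSC minus PGC (81.9%), and 15364 and 807 for SSC minus ESC (95.0%). The pluripotency medians became -1.50, -0.21 and -2.62 in the same order, the germ cell medians -0.07, 2.56 and 3.55, and the spermatogonial medians 1.41, 0.16 and 1.72. Without the filter on dim probes the germ cell median of SSC minus PGC was 2.61, as genes at the floor of the PGC array then enter. With spike-in scaling the medians of gastrulation genes (0.74) and of DNA methylation and chromatin genes (0.44) for SSC minus ESC, and of FGF and MAPK genes (0.05) and dissociation genes (0.64) for SSC minus PGC, turned positive, as did the medians nearer to 0 that lay within the random lists. The dissociation median also turned with quantile normalization (0.45) and the deposited values (0.47), the cause was not tested, and the ribosomal protein median of SSC minus ESC turned to -0.26 with median scaling, which shifts all genes. The median over a gene's probes turned CDH1 (-0.04) and AMH (1.03) for PGC minus ESC, as their probes disagree. Of the other list medians, over all settings, 559 were within their standard error and 130 moved beyond it, 74 of them with spike-in scaling. Of gene values 1847 stayed within the SD per probe, from 2 probes of one gene, and 527 moved beyond it, 320 of them with spike-in scaling. Stage-highest counts stayed within 1.5 times with normexp and quantile normalization, the settings they were run with. No paired analysis was possible because each stage has 1 array. Signal over background limits dim genes to bounds. It also makes the size of a difference uncertain where a measured signal lies near the floor, such as CDX2 at -6.62 on the SSC array.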

Other observations

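The gene lists here were written after the data had been seen and hold genes picked for their large differences, such as CTSG, TMEM52B and UPK3B, so their medians and counts are no independent evidence of a direction. Genes of heterophil granules, the antimicrobial stores of the bird's counterpart of neutrophils, had a median PGC minus ESC of 4.63 (SE 1.05), with 12 of 13 members at least 2-fold higher, and a median SSC minus PGC of 2.61 (SE 0.34), with 15 of 17 higher. CATH2 stood at 9.0 and DEFB4A at 7.48 for PGC minus ESC, and CTSG at 8.14 and LYG2 at 3.75 for SSC minus PGC. This list shares 1 member each with the leukocyte and JAK-STAT lists. Genes of the mesonephros, the kidney of the embryo that lies beside the gonads, had a median PGC minus ESC of 2.83 (SE 0.45), with 16 of 21 members higher and 1 lower, and a median SSC minus PGC of -2.79 (SE 0.87), with 15 of 19 lower and 1 higher. TMEM52B stood at 8.40 and PAX2 at 6.44 for PGC minus ESC, and UPK3B at -8.27 for SSC minus PGC. Of this list, 3 members are also in the gastrulation list and 1 each in the Sertoli cell and spermatogonial lists.

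Of the probes that the files place on the W chromosome, 54 in all, 50 were well above background on the ESC array, 49 on the PGC array and 38 on the SSC array. Of all probes, 86.96%, 86.85% and 86.25% were well above background on these arrays. Besides the HINTW probes, 9 of the W probes were at least 16-fold lower on the SSC than on the PGC array. The share of all probes with such a fall is not given here, and whether W probes detect Z-linked copies was not tested.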
